A study of Rattus norvegicus with 8 samples.

How the data were processed

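RNA was taken from A2B5+ and GalC+ cells sorted by flow cytometry from whole brains of rats at postnatal day 7, with 4 biological replicates per population and 1 pooled litter of 10 pups per replicate. Per the labels' protocols, total RNA was extracted with a column kit, labelled with biotin by Affymetrix's procedure for small samples, and hybridised with 1 colour, 1 array per replicate. The signals were summarised with RMA, per the submitters' processing notes; its version is not given in the sources used here. The deposited values are a linear ratio of each probe set's signal to that probe set's median over the 8 arrays. This is seen in the values and not stated: all 31099 deposited rows have a median of 1 within 0.0015, and no value is negative. The division keeps the fold between any pair of arrays and removes the level, so that a bright probe set cannot be told from a dim one and signal over background cannot be judged. A probe set near background has its fold compressed, and such probe sets could not be set aside.

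The ratios were log2 transformed without a pseudocount and not normalised further. After leaving out 57 Affymetrix control probe sets, 31042 were tested. Probe sets were named through the platform's gene annotation: 20826 had 1 gene symbol, 436 had several and 9780 had none, and only those with 1 symbol were used for genes. Of these, 20758 had a gene ID found in the RefSeq gene table of the rat (assembly GRCr8), which was used only for names and changed 0 symbols. No genome positions are given, because the arrays' values carry none. This left 14217 genes, 4525 of them with several probe sets. All columns of values belonged to a sample of the series.

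Each gene was read from the probe set with the largest variance over all 8 arrays. The plan, made before the data were examined, was to use the brightest probe set, which could not be done once the level was found to be removed. The largest variance was among the alternatives listed beforehand, but it was preferred to the mean of a gene's probe sets only after the file had been opened and the values of some genes, Ugt8 among them, had been seen with both. It takes the larger fold where probe sets of a gene disagree. In data simulated without a group difference, 5.41% of genes had p under 0.05 with this rule and 5.19% with the mean. Of 93 genes named by the rule below, 39 had several probe sets; in 21 all gave the same call, and in 0 did any give the opposite call.

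GalC+ was compared with A2B5+ with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all probe sets or all genes and a threshold of 0.05. Replicate numbers were not used as a block, since nothing in the labels says that a number marks a shared litter. The 26 gene lists were fixed before the data were examined, and were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. Members were also counted with the adjustment over the list alone. Some genes stand in more than 1 list, Hes5, Sox11, Pdgfra and Dcn among them. The error of a list mean is the SE of the difference between the 4 array means of each population. Exact permutation tests were two-sided over all 35 splits of the 8 arrays into 4 and 4. Replicates of a population are from separate litters, so p values refer to the spread between litters and the handling of each sort. Whether A2B5+ and GalC+ arrays with the same number share a litter is not stated, and the p values take them as separate. Neither the labels nor the values used here give a scan date or another batch, so none could be tested.

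The genes named were chosen by a rule set before the data were examined: the 10 largest rises and the 10 largest falls among genes past the threshold whose groups do not overlap, up to 2 rises and 2 falls from each list, or the largest difference where none passed, and fixed markers of the sorted stages. One of the fixed markers is not reported here. A few genes outside the rule complete counts of 5 or fewer and are named as such.

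The fit was tested on data simulated with the spread of these 8 arrays, over 31042 probe sets. It recovered 37 of 68 probe sets changed by 0.5 on the log2 scale (54.4%), 60 of 66 at 1 (90.9%) and 66 of 66 at 2 (100%). There were 14 false calls. The noise was drawn independently for each probe set, and far fewer probe sets were changed than the 8313 called in the real data. Recovery and the share of false calls in the real data can therefore differ. Each alternative kept the probe set chosen for a gene on all 8 arrays, apart from the mean of a gene's probe sets. The alternatives were a replicate block, quantile normalization, median centring, a trended and robust prior, a Welch statistic, array weights, leaving out each array in turn, the mean of a gene's probe sets, camera with an estimated correlation, fry, an adjusted p under 0.01, and limma's treat against a fold of 1.2. The Welch statistic takes its spread from each gene or probe set alone. With it, and with the trended and robust prior, lists were tested with limma's cameraPR on the genes' t statistics. The list test changed there as well, so that a changed list call cannot be credited to the spread or the prior. A planned filter on dim probe sets could not be run without levels, and a filter on variance was added after seeing the data.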

Results

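The series measured transcript levels in oligodendrocyte-lineage cells sorted by flow cytometry from whole brains of rats at postnatal day 7. Cells carrying A2B5, a ganglioside epitope found on glial progenitors, were compared with cells carrying galactocerebroside (GalC), a lipid of oligodendrocytes and myelin. The labels name the first population as oligodendrocyte progenitors and the second as oligodendrocytes. Each population had 4 biological replicates, each from 1 pooled litter of 10 pups, and each replicate was hybridised to 1 Affymetrix array. The deposited values are ratios of each probe set's signal to its own median over the 8 arrays, so that they carry differences between arrays but not the brightness of a probe set. The median ratio per array lay between 0.979 (A2B5+ replicate 2) and 1.03 (GalC+ replicate 2). The SD of log2 differences between arrays was 0.21 to 0.34 within a population and 0.42 to 0.68 between populations, and the first principal component, which separated the populations, held 73.0% of the variance. With 4 arrays per population, the number of arrays limits the precision; the median SE of a log2 fold change was 0.099. The title of the series names regulated networks of microRNA and mRNA; here only mRNA was analysed.

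The haemoglobin scavenger receptor Cd163 was 42.7-fold higher in GalC+ than in A2B5+ cells (log2 fold change 5.41 ± 0.20 SE, n = 4 and 4), and the myelin gene Mobp was 38.2-fold higher (5.26 ± 0.38; mean of its 3 probe sets 4.08). Eomes, a transcription factor of intermediate progenitors of neurons, was 7.03-fold lower (-2.81 ± 0.51, mean of its 2 probe sets -2.38). Stmn2, a growth-associated protein of neurons, was 6.35-fold lower (-2.67 ± 0.25, mean of its 2 probe sets -2.23). In total 5079 of 14217 genes changed (limma, adjusted p under 0.05), of which 2585 were higher and 2494 lower in GalC+. Changes of at least 2-fold were found in 677 genes that were higher and 377 that were lower. At 4-fold the counts were 157 and 34, and at 8-fold 58 and 0. By probe set, 8313 of 31042 changed (26.8%), 4204 higher and 4109 lower, and 1622 of them changed at least 2-fold. The values of the 4 A2B5+ arrays did not overlap those of the 4 GalC+ arrays in 36.2% of genes, against 2.86% by chance. With a spread estimated for each probe set alone, 4420 probe sets changed, and 4911 had an adjusted p under 0.01 in limma.

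**Figure D1:**
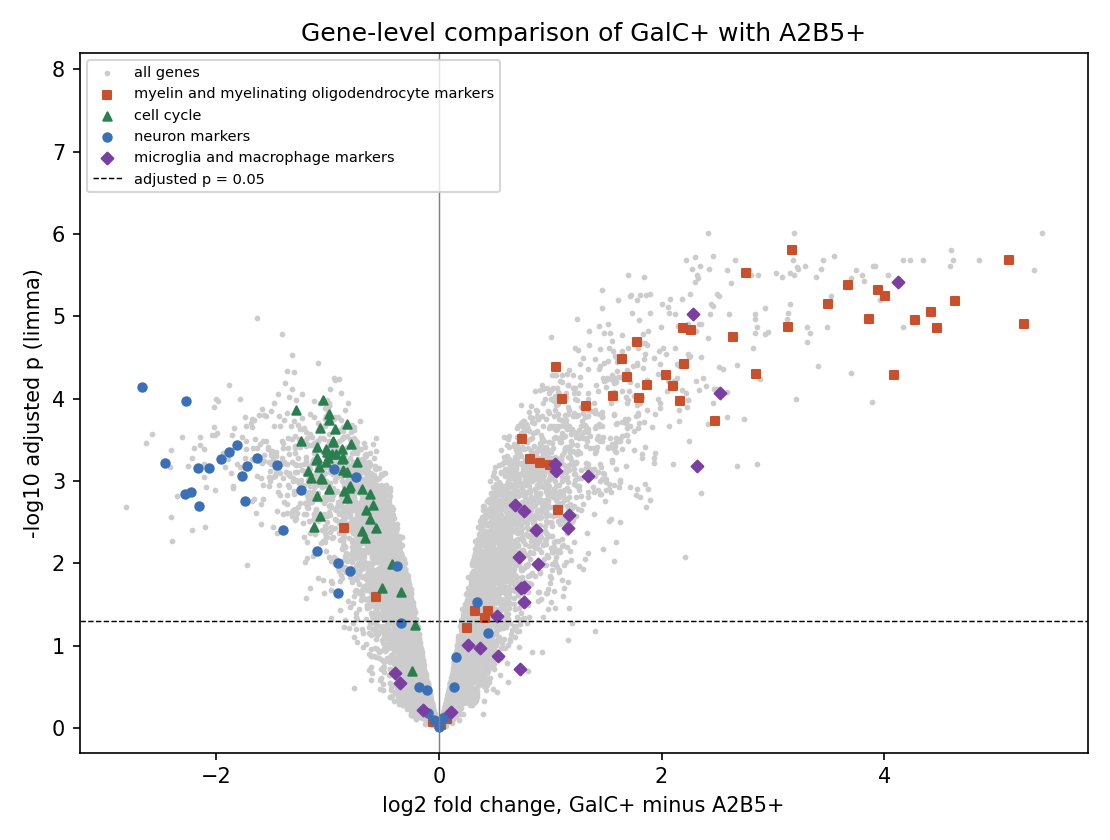
Log2 fold change (GalC+ minus A2B5+, horizontal axis) against -log10 of limma's adjusted p (vertical axis) for each of 14217 genes (grey points), with 4 gene lists marked by colour and shape and a dashed line at an adjusted p of 0.05. Myelin markers reach a log2 fold change of 5.26, cell cycle genes lie to the left at a list mean of -0.87, and neuron markers reach -2.67.

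Among the 10 genes with the largest rise, Mobp, Ermn, Klk6 and Mal belong to myelin or myelinating oligodendrocytes. Ermn, which encodes a cytoskeletal protein of oligodendrocytes, was 34.9-fold higher in GalC+ (log2 fold change 5.13 ± 0.25 SE, adjusted p = 2.06e-06; mean of its 3 probe sets 3.48), and Mal, a proteolipid of compact myelin, was 22.2-fold higher (4.47 ± 0.33, adjusted p = 1.40e-05). Klk6, a secreted serine protease of mature oligodendrocytes, was 24.8-fold higher (4.63 ± 0.30, adjusted p = 6.44e-06). The other 6 were Cd163, F13a1, Ccr1, Clec10a, Igsf6 and Plbd1. F13a1, the A chain of coagulation factor XIII, was 40.6-fold higher (5.34 ± 0.29, adjusted p = 2.74e-06; mean of its 2 probe sets 3.95), and the chemokine receptor Ccr1 was 28.9-fold higher (4.85 ± 0.23, adjusted p = 2.06e-06). The lectin Clec10a (24.5-fold, 4.61 ± 0.22), the immunoglobulin superfamily gene Igsf6 (24.2-fold, 4.60 ± 0.19) and the phospholipase-like gene Plbd1 (24.1-fold, 4.59 ± 0.24) followed. Plbd1 was read from 1 of its 2 probe sets; the other showed 0.18, and the mean of both was 2.39.

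Among the 10 genes with the largest fall, Stmn2 and Dlx1 belong to the fixed list of neuron markers. The transcription factor Neurod1 was 5.34-fold lower in GalC+ (log2 fold change -2.42 ± 0.35 SE, adjusted p = 6.71e-04), Dlx1, a factor of inhibitory interneurons, was 5.51-fold lower (-2.46 ± 0.35, adjusted p = 5.96e-04), and Bcl11a was 6.19-fold lower (-2.63 ± 0.33, adjusted p = 3.45e-04). Bcl11b was 5.30-fold lower (-2.41 ± 0.46, adjusted p = 0.00278). B3gnt5, a glycosyltransferase that makes lacto-series glycolipids, was 5.96-fold lower (-2.57 ± 0.31, adjusted p = 2.68e-04). Nol4 (5.30-fold, -2.41 ± 0.32; its other probe set -0.50, mean of both -1.45) and Nxph1, a secreted ligand of neurexins that was also among the fixed progenitor markers (5.11-fold, -2.35 ± 0.40), were lower too. The mean of the 3 probe sets of Nxph1 was -1.97. With the spread estimated for each gene alone Nxph1 had an adjusted p of 0.0618. Mcpt1l1, a mast cell protease gene, was 5.28-fold lower (-2.40 ± 0.52, adjusted p = 0.00535), with a wide spread among A2B5+ arrays (ratio 3.09 ± 1.81 SD, n = 4).

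**Figure D2:**
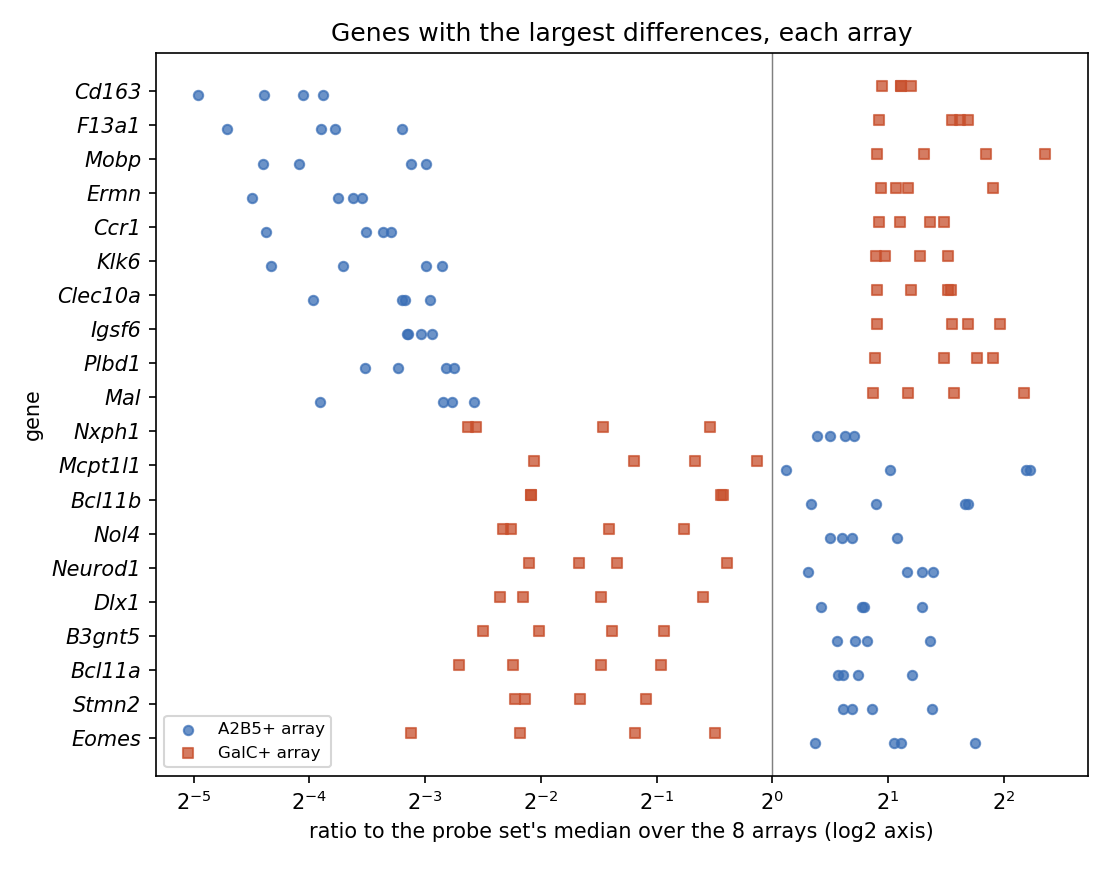
Ratio to the probe set's median over the 8 arrays (log2 axis) for the 10 genes with the largest rise and the 10 with the largest fall, 1 circle per A2B5+ array and 1 square per GalC+ array. For Cd163 the A2B5+ arrays average 0.052 and the GalC+ arrays 2.14; the groups do not overlap for any of the genes drawn, which the rule for choosing them required.

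The genes fixed in advance as markers of the sorted stages were read next. Ugt8, the enzyme that makes the sorted antigen galactocerebroside, was 14.9-fold higher in GalC+ (log2 fold change 3.89 ± 0.40 SE, adjusted p = 1.10e-04). This was read from 1 of its 2 probe sets; the other showed 0.02, and the mean of both was 1.96. The myelin genes Mbp (14.6-fold, 3.86 ± 0.27, adjusted p = 1.08e-05; mean of its 3 probe sets 2.50) and Mog (21.4-fold, 4.42 ± 0.30, adjusted p = 8.96e-06) were higher, as was Sox10, a transcription factor of the whole lineage (2.90-fold, 1.54 ± 0.19, adjusted p = 3.04e-04). Pmp22, a myelin protein of peripheral nerve, was 1.68-fold higher (0.75 ± 0.09, adjusted p = 3.05e-04). Pdgfra, the receptor that drives progenitor division, was 2.40-fold lower (-1.26 ± 0.23, adjusted p = 0.00208), and the proliferation marker Mki67 was 1.62-fold lower (-0.69 ± 0.14, adjusted p = 0.00402). No difference was detectable for the progenitor proteoglycan Cspg4 (0.01 ± 0.15, adjusted p = 0.962, 95% interval -0.33 to 0.36), whose sign turned with the scaling of the arrays. The lineage factor Olig2 (0.04 ± 0.08, adjusted p = 0.702, 95% interval -0.14 to 0.22) and the astrocyte filament gene Gfap (0.17 ± 0.13, adjusted p = 0.322, 95% interval -0.11 to 0.45) did not pass the test either.

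Markers of myelin and of myelinating oligodendrocytes rose together. Of 47 measured members, 41 were higher in GalC+, 2 were lower and the rest did not pass the test, and the mean log2 fold change was 2.12 ± 0.16 SE. Adjusted over the list alone, 42 were higher and 2 lower. Mobp and Ermn led the list. The lower members were the adhesion molecule Cntn2 (-0.85, adjusted p = 0.00375) and Trim59 (-0.56, adjusted p = 0.0257), whose call was lost in 5 of the 8 fits that left out 1 array (highest adjusted p = 0.0688). Markers of committed progenitors and newly formed oligodendrocytes had a mean of 1.43 ± 0.16, with 17 of 20 higher and 1 lower, both over all genes and adjusted over the list alone. The semaphorin Sema4d (4.03) and the calcium-sensing receptor Casr (3.82) rose most, and the adhesion molecule Nrcam fell (-0.49, adjusted p = 0.0371), a call lost in 3 of the 8 fits that left out 1 array (highest adjusted p = 0.0976). Progenitor markers had a mean of -0.57 ± 0.08 and a median of -0.45, with 13 of 26 lower and 2 higher. The other 11 did not pass, Cspg4 among them. Adjusted over the list alone, 15 were lower and 2 higher. Nxph1 and the transcription factor Sox11 (-2.21) fell most. Olfml2b (0.57, or 0.34 as the mean of its 2 probe sets) and Sez6l (0.55) were the members that rose; without A2B5+ replicate 2 the adjusted p of Sez6l was 0.0525. With the spread estimated for each gene alone, Trim59 (adjusted p = 0.0945), Nrcam (0.134) and Sez6l (0.0821) did not pass. The camera test gave an adjusted p of 1.77e-21 for the myelin list, 7.93e-09 for the newly formed oligodendrocytes and 4.81e-04 for the progenitors, and each had an adjusted p = 0.265 with an estimated correlation. Neuron markers were lower in GalC+ beside the progenitor markers (list mean -1.09), and macrophage (0.96) and mural cell (1.2) markers were higher beside the myelin markers.

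Of 22 enzymes and regulators of cholesterol synthesis, 16 were higher in GalC+ and none lower (17 higher adjusted over the list alone), with a mean of 0.53 ± 0.10 SE; Hsd17b7 (1.09) and lanosterol synthase Lss (1.02) led. The list had a camera adjusted p of 2.59e-06, and an adjusted p = 0.289 with an estimated correlation. Of 12 genes that make or turn over galactolipids, 6 were higher and 0 lower (7 higher adjusted over the list alone), with a mean of 0.95 ± 0.11 and a median of 0.41. Ugt8 and the fatty acid hydroxylase Fa2h (2.80) had the largest rises (camera adjusted p = 0.00536, and adjusted p = 0.286 with an estimated correlation). Fatty acid synthesis and elongation had 8 of 22 members higher and 1 lower, as it had adjusted over the list alone, at a mean of 0.38 ± 0.11. Acsl1 (1.70, mean of its 3 probe sets 1.14) and Elovl1 (1.57) rose. Elovl2 fell (-0.42, adjusted p = 0.0397), a call lost in 6 of the 8 fits that left out 1 array (highest adjusted p = 0.109). Camera gave this list an adjusted p of 0.0124, and it had an adjusted p = 0.557 with an estimated correlation. The ganglioside enzymes, which make the class of lipid that A2B5 binds, went both ways. Of 12 measured, 7 were higher, led by the sialyltransferases St8sia3 (1.13) and St6galnac3 (1.11), and 3 were lower, St6galnac5 (-0.96), St3gal2 (-0.68) and B4galnt1 (-0.37), the last named only after the values were seen. St3gal2 was read from 1 of its 2 probe sets, and the mean of both was -0.41. These counts were the same adjusted over the list alone. The mean was 0.25 ± 0.04 and the list did not pass the camera test (adjusted p = 0.133). With the spread estimated for each gene alone, Elovl2 (adjusted p = 0.124), St6galnac3 (0.0536) and St3gal2 (0.0658) did not pass. Macrophage (0.96) and mural cell (1.2) markers were higher in GalC+ beside the lipid lists.

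Cell cycle genes were lower in GalC+ nearly throughout. Of 52 members measured, 50 were lower and none higher, or 51 and none adjusted over the list alone, at a mean of -0.87 ± 0.12 SE. The kinetochore gene Spc25 (-1.29) and Racgap1 (-1.24), which acts in cell division, fell most, and neuron markers (-1.09) fell beside them. The camera adjusted p was 3.74e-23, and the list had an adjusted p = 0.265 with an estimated correlation.

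Transcription factors reported to hold back oligodendrocyte differentiation fell in 10 of 18 cases and rose in none, with the same counts adjusted over the list alone and a mean of -0.57 ± 0.07 SE. Sox11 and the Notch effector Hes5 (-1.59) fell most; a further probe set of Hes5 showed 0.05, and the mean of both was -0.77. Neuron markers (-1.09) were lower in GalC+ beside this list, and Sox11 is also expressed by young neurons. The list had a camera adjusted p of 7.89e-04, and an adjusted p = 0.265 with an estimated correlation. Of 16 factors reported to favour differentiation, 7 were higher and 2 lower by both adjustments, at a mean of 0.68 ± 0.08 and a median of 0.23. Nkx6-2 (3.03) and Myrf (2.26), which switch on myelin genes, rose most. Nfia, which also acts in astrocyte formation, fell (-0.97, mean of its 3 probe sets -0.63), and Olig1 fell (-0.35, adjusted p = 0.0241), a call lost in 3 of the 8 fits that left out 1 array (highest adjusted p = 0.0683) and with the spread estimated for each gene alone (0.0551). This list missed the threshold of the camera test (adjusted p = 0.0508), and passed it in several other settings.

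Of 8 measured transcripts reported elsewhere as targets of miR-219 or miR-338, microRNAs of oligodendrocytes, 5 were lower and 1 higher (6 and 1 adjusted over the list alone), with a mean of -0.84 ± 0.14 SE. The lower ones were Neurod1, Hes5, Pdgfra, Zbtb18 (-0.78) and Etv5 (-0.42), and the higher one was the growth factor receptor Fgfr2 (0.51, from 1 of its 5 probe sets; no other passed the test, and the mean of all was 0.22). Zbtb18 and Etv5 were named after the values were seen. Camera gave an adjusted p of 0.0145, and the list had an adjusted p = 0.265 with an estimated correlation and 0.103 with the spread estimated for each gene alone. Neuron markers (-1.09), a group that Neurod1 goes with, were lower as well. Genes that make or carry microRNAs did not move one way (mean -0.03 ± 0.03, camera adjusted p = 0.574). Of 19 measured, Ago3 (0.48), Dicer1 (0.47, mean of its 2 probe sets 0.36) and Mov10 (0.26, named after its value was seen) were higher. Ddx20 (-0.47) and Prkra (-0.35) were lower. Adjusted over the list alone, 2 were higher and 2 lower. With the spread estimated for each gene alone, Ago3 (adjusted p = 0.051), Dicer1 (0.0827) and Ddx20 (0.0767) did not pass.

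Receptors for glutamate and GABA had 7 of 28 members lower and 1 higher (6 and 1 adjusted over the list alone), at a mean of -0.26 ± 0.03 SE. Gria1 (-1.02) and Gabrb2 (-0.76) fell most, and Grm7 was higher (0.29, adjusted p = 0.035), a call lost in 6 of the 8 fits that left out 1 array (highest adjusted p = 0.0902). The other probe set of Gabrb2 showed 0.18, and the mean of both, -0.29, did not pass (adjusted p = 0.087). The camera adjusted p was 0.0206, and the list had an adjusted p = 0.265 with an estimated correlation and 0.0757 with the spread estimated for each gene alone. Voltage-gated sodium and potassium channels had 13 of 26 lower and 2 higher (14 and 3 adjusted over the list alone), at a mean of -0.19 ± 0.03. Kcnd3 (-1.28) and Scn3b (-0.90) fell, whereas Kcna6 (1.78) and Kcna1 (1.62) rose. Over their 3 probe sets each, the mean was 0.69 for Kcna6, where no other probe set passed, and -0.83 for Kcnd3. For this list the camera adjusted p was 0.0209, and it had an adjusted p = 0.265 with an estimated correlation and 0.0966 with that spread. Many of these genes are also expressed by neurons, whose markers were lower in GalC+ (-1.09). Notch, Wnt and BMP signalling had 13 of 34 members lower and 2 higher by both adjustments (mean -0.19 ± 0.05) and missed the threshold of camera (adjusted p = 0.0508), which it passed with the mean of a gene's probe sets (0.0319), array weights (0.0346) and in several other settings. Sfrp2 (-1.64, mean of its 2 probe sets -1.19) and Hes5 fell most. The ligands Bmp2 (2.46, mean of its 2 probe sets 2.06) and Bmp4 (1.57) rose. With the spread estimated for each gene alone, Gabrb2 (adjusted p = 0.0761), Grm7 (0.0574), Kcna1 (0.0566) and Sfrp2 (0.0708) did not pass.

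Extracellular matrix proteoglycans and tenascins were split, with 6 of 29 higher and 7 lower (7 and 9 adjusted over the list alone). Decorin (Dcn, 1.78), which was also counted among fibroblast markers, and tenascin-R (Tnr, 1.72) rose, and Gpc2 (-1.16) and Sdc1 (-0.76) fell. The mean was 0.06 ± 0.07 SE, the median -0.12, and the camera test leaned downward without passing (adjusted p = 0.574). Ribosomal protein genes did not pass as a list (mean -0.07 ± 0.03, adjusted p = 0.204); Rpl28 (-0.81), Rps24 (-0.62) and Rps13 (-0.55, named after its value was seen) were lower and none higher of 42, or 1 lower adjusted over the list alone. For Rps24 the mean of 2 probe sets was -0.28, and its adjusted p was 0.0911 with the spread estimated for each gene alone. Of 79 oxidative phosphorylation genes, Cox4i2 (0.85) and Cox7a1 (0.29) were higher and Cox6b2 (-0.98) and Ndufa7 (-0.59) lower, or 1 higher and 2 lower adjusted over the list alone. The call of Cox7a1 was lost in 3 of the 8 fits that left out 1 array (highest adjusted p = 0.0598). The other probe set of Ndufa7 showed 0.17, and the mean of both, -0.21, did not pass (adjusted p = 0.0806). The mean of the list was 0.004 ± 0.04, while camera's sign was negative (adjusted p = 0.783), and the sign of the mean turned with the scaling of the arrays.

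Markers of cell types other than the oligodendrocyte lineage differed between the sorted populations. Neuron markers had 25 of 37 members lower in GalC+ and 1 higher (26 and 2 adjusted over the list alone), with a mean of -1.09 ± 0.18 SE. Stmn2 and Dlx1 fell most, and Elavl3 rose (0.34, adjusted p = 0.0292, from a probe set that may bind other transcripts; the other showed 0.31), a call lost in 5 of the 8 fits that left out 1 array (highest adjusted p = 0.0799) and with the spread estimated for each gene alone (0.0641). Microglia and macrophage markers had 18 of 26 higher and none lower by both adjustments, at a mean of 0.96 ± 0.23; the mannose receptor Mrc1 (4.12) and Cd14 (2.52) rose most. Markers of mural cells and fibroblasts had 21 of 25 higher and none lower (22 higher adjusted over the list alone), at a mean of 1.2 ± 0.19, with the smooth muscle genes Myh11 (3.13) and Tagln (2.68) ahead. The other probe set of Myh11 showed 0.18, and the mean of both was 1.65. Camera gave adjusted p values of 1.32e-08 for neurons, 2.19e-06 for macrophages and 5.06e-09 for mural cells. With an estimated correlation the adjusted p was 0.265 for neurons, 0.432 for macrophages and 0.279 for mural cells.

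Astrocyte markers had 3 of 22 members lower and none higher by both adjustments (mean -0.29 ± 0.16 SE). These were Hes5, Gli2 (-0.52) and Mlc1 (-0.36), the last named after its value was seen. The camera adjusted p was 0.0209, with an adjusted p = 0.60 with an estimated correlation, 0.12 without GalC+ replicate 2 (mean -0.19) and 0.102 with the spread estimated for each gene alone. Endothelial markers did not differ as a list (mean -0.03 ± 0.30, adjusted p = 0.665). Of 23, Egfl7 was higher (0.74, adjusted p = 0.0477, from a probe set that may bind other transcripts), and Ly6e was lower (-0.73, mean of its 2 probe sets -0.51). The call of Egfl7 was lost in 5 of the 8 fits that left out 1 array (highest adjusted p = 0.114), its value was 0.49 without A2B5+ replicate 2, and neither of its 2 probe sets passed when adjusted over all probe sets. Adjusted over the list alone, 0 were higher and 1 lower. No erythroid marker of 10 passed the test by either adjustment (mean -0.04 ± 0.11, list adjusted p = 0.754), and Rhd had the largest difference (-0.27, adjusted p = 0.151). Ependyma and choroid plexus markers had 3 of 12 lower and none higher by both adjustments, Dynlrb2 (-0.63), Foxj1 (-0.58) and Tekt1 (-0.53, named after its value was seen), and did not pass as a list (mean -0.24 ± 0.11, adjusted p = 0.0644), though it passed with array weights (0.0467) and in some other settings. The call of Foxj1 was lost in 2 of the 8 fits that left out 1 array (highest adjusted p = 0.0621). With the spread estimated for each gene alone, Egfl7 (adjusted p = 0.144), Ly6e (0.0579) and Foxj1 (0.124) did not pass.

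Transcripts that tissue dissociation and sorting can raise were higher in GalC+ in 15 of 30 cases and lower in none (16 higher adjusted over the list alone), at a mean of 0.51 ± 0.16 SE. Gadd45b (1.5) and the haem oxygenase Hmox1 (1.34), which macrophages also express, rose most. Macrophage markers were higher beside them (0.96), and A2B5+ replicate 3 was the highest A2B5+ array in both lists (mean log2 ratio 0.05 against -0.46 to -0.38 for the stress list, and -0.04 against -0.86 to -0.59 for macrophages). The list had a camera adjusted p of 5.88e-04 and an adjusted p = 0.496 with an estimated correlation. The 3' to 5' log2 ratios of control transcripts, a sign of RNA integrity, differed by -0.17 for beta-actin, -0.06 for GAPDH and -0.03 for hexokinase (exact permutation p = 0.457, 0.80 and 0.743), so that no difference was detectable with 4 arrays against 4. These ratios varied more among the GalC+ than the A2B5+ arrays. The SD was 0.42 against 0.17 for beta-actin, 0.41 against 0.13 for GAPDH and 0.17 against 0.08 for hexokinase. The added bacterial and phage control probe sets differed by 0.10 (exact permutation p = 0.114).

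**Figure D3:**
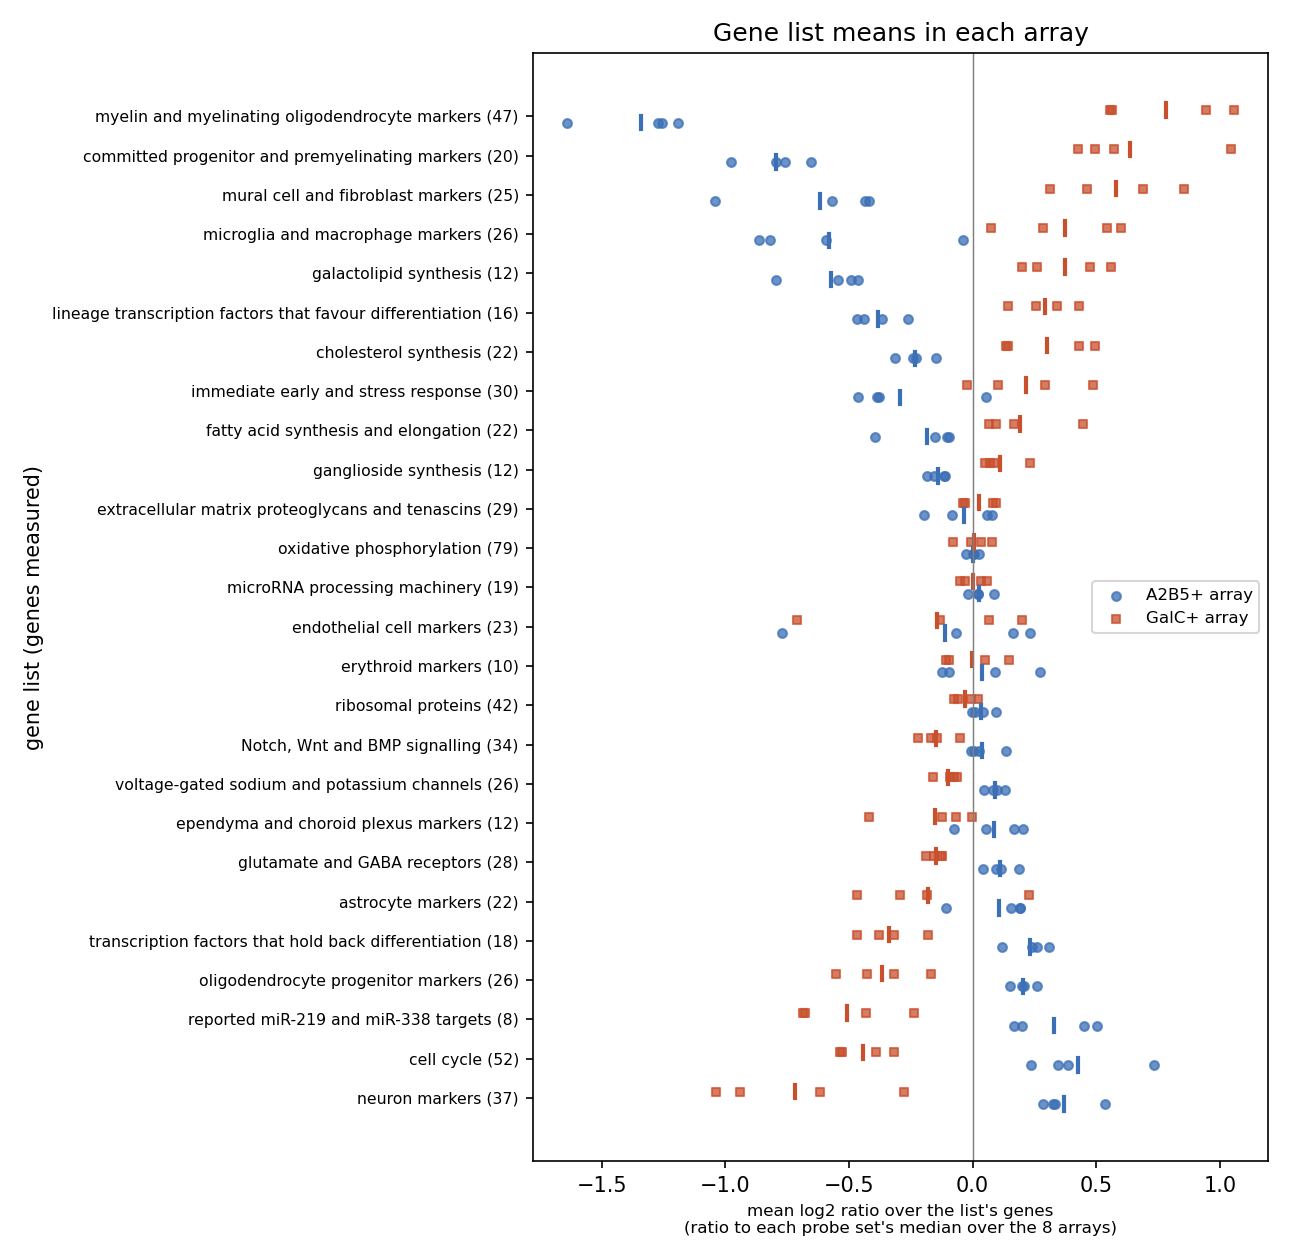
Mean log2 ratio over the measured members of each of 26 gene lists (horizontal axis; number of genes measured in brackets), 1 circle per A2B5+ array and 1 square per GalC+ array, with a vertical tick at the mean of each group of 4. The lists are ordered by their difference, from -1.09 for neuron markers at the bottom to 2.12 for myelin markers at the top.

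Of the 26 lists, 16 passed the camera test at a preset correlation of 0.01, 8 higher and 8 lower in GalC+. None passed with an estimated correlation (4 had an unadjusted p under 0.05), whereas the rotation test fry, which asks whether a list's own genes move one way, called 17, of which 15 were shared with camera. The number of lists passing camera was not the highest among the 35 ways to split the 8 arrays into 4 and 4: 4 of them, the real one included, gave at least 16, up to 19. The other 3 of these splits exchanged 1 array between the populations, and splits that exchanged 2 gave at most 11. For 17 lists the difference in list mean between the populations was the largest of all 35 splits (exact permutation p = 0.0286 each, the smallest 4 against 4 can give, and 0.0437 after adjustment over the 26 lists). The called lists whose means did not reach this were astrocyte markers (exact permutation p = 0.143) and the dissociation and stress transcripts (0.0571).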

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

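The tests of macrophage, microglia and neuron transcripts below were chosen after the lists had been seen, except that the further border macrophage markers were written down before any of their values had been looked at; the splits of the arrays were planned.

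In 14 of 242 groups of 4 arrays, over list means, named genes and the SD and median of each array, 1 array stood so far from the other 3 that its gap to the nearest of them exceeded Dixon's 95% limit, as a share of the whole range. Chance singles out about 1 in 20 such groups, 12.1 here, so that their number is near what chance gives. The groups come from the same 8 arrays and are not independent, and the flags were not spread evenly. A2B5+ replicate 2 accounted for 8 of the 14, and it had the largest SD of log2 ratios among the 8 arrays (0.38). This array was lower than the other A2B5+ arrays for the astrocyte list (gap 0.878 of the range). The same held for Acsl1 (0.891), Bmp2 (0.906), Egfl7 (0.844), Elovl1 (0.879), Mog (0.851) and Mrc1 (0.885), and it was higher for Elavl3 (0.906). GalC+ replicate 4 was lower than the other GalC+ arrays for Mrc1 (0.939) and Pmp22 (0.869) and higher for Ndufa7 (0.845). A2B5+ replicate 3 was higher for the dissociation and stress list (0.835), A2B5+ replicate 4 for Sox10 (0.904), and A2B5+ replicate 1 for St3gal2 (0.831).

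Transcripts of macrophages and of mural cells were higher in GalC+, a sort meant for oligodendrocytes. A lower share of oligodendrocytes that raises every other cell type alike is argued against by the endothelial list, whose shift was 0.99 below that of the macrophage list (difference -0.99, exact permutation p = 0.0286, the smallest possible). More microglia in the sort is argued against by their homeostatic markers, for microglia that keep these markers. The markers shifted by -0.24 (1 of 6 lower, none higher), which is within their spread (exact permutation p = 0.286). They were highest in A2B5+ replicate 3 (mean ratio 1.59). Their shift lay below that of the genes shared with other macrophages (0.86) by -1.10 (exact permutation p = 0.0286). Whether microglia in the GalC+ sort had lost these markers was not tested. Macrophages of the brain's borders, which the GalC gate is meant to remove, may be a source: their markers Cd163, F13a1 and Mrc1 rose by 4.12 or more, and of 18 further markers written down the 6 that were measured all rose (median 1.38), though some of these, such as Igf1, Gas6 and Tgfbi, are also expressed by other brain cells. Why mural cell transcripts were higher stays open, and a difference in the cells' own expression was not tested.

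Neuron transcripts were higher in A2B5+. The mural cell list cannot decide whether a lower share of progenitors raised all other types alike. It was lower in A2B5+ (GalC+ minus A2B5+ 1.2, exact permutation p = 0.0286). Why it was higher in GalC+ stays open, and a source in GalC+ would give this sign whatever the share of progenitors in A2B5+. Whether progenitors express early neuron genes themselves, with no neurons in the sort, cannot be told apart from neurons or neuronal precursors that carry A2B5. Genes that give neurons their transmitter had a mean shift of -0.54 (exact permutation p = 0.0286), which by the test as first set would have counted against the progenitors' own expression, and the verdict was withheld only after this value was seen. The reason is that 3 of 11 members, Gad1 (-2.28), Slc17a6 (-1.88) and Slc32a1 (-1.73), carried it and the median was -0.10.

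Other splits of the 8 arrays into 4 and 4, of which there are 35, gave far fewer calls than the real one. The other splits mix the populations, so that the difference between the sorts widens their spread and low counts there are partly built in. For the probe sets changed, only the real split gave as many (1 of 35 splits, 8313 against at most 1 in any other). This is the smallest share that 35 splits can give (exact permutation p = 0.0286), which makes chance unlikely but does not exclude it. The same held for probe sets higher in GalC+ (1 split; 4204 against at most 1), lower (1 split; 4109 against at most 1), changed at least 2-fold (1 split; 1622 against at most 1), and for genes (1 split; 5079 against at most 1). For the number of gene lists passing camera with its preset correlation, chance cannot be excluded: 4 of the 35 splits gave 16 or more, with 19 the highest, although 0 genes changed in the other 3 of these splits. Those 3 each kept 3 arrays of a population together against 1 that crossed over, so that they still hold part of the difference between the sorts; splits with 2 arrays of each population on either side gave at most 11.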

How the results depend on the processing

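The filter on variance was chosen after seeing the data, and a planned filter on dim probe sets was not run, because the deposited ratios hold no signal level; for the same reason signal over background cannot limit any statement here. Counts of changed probe sets and genes stayed within 1.5 times of the reported ones in all but 4 comparisons. The Welch statistic gave 4420 probe sets (2397 higher, 2023 lower), and an adjusted p under 0.01, a stricter threshold by construction, gave 4911. Leaving out 1 array gave 6416 to 8463 probe sets. Single named genes were not run with the stricter threshold, treat, fry or camera with an estimated correlation. Of 93 named genes, 69 kept their call and 92 their direction in every setting in which they were run. The exception was Cspg4, never past the test, which turned to -0.0156 with quantile normalization, -0.0159 with median centring, -0.0509 with array weights, and ranged from -0.12 to 0.11 with 1 array left out.

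The replicate numbers were not taken to pair the arrays, since the labels name nothing shared and 1 of 4 correlations between deviations of arrays with the same number was under 0.1 (0.40, 0.09, 0.30 and 0.17). That 6 of 8 arrays correlated best with their own number (mean 0.24) is a hint from the data, and pairing stays unsettled. The mean of -0.08 for other numbers is no baseline, since it follows largely from taking deviations from each population's mean. With a replicate block, 9194 probe sets changed (4506 higher, 4688 lower), and the lists for Notch, Wnt and BMP signalling (-0.19) and ependyma (-0.24) passed the test, and Grm7 did not (adjusted p = 0.0572).

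With an estimated correlation none of the 16 called lists passed, at the same means: progenitors -0.57, newly formed oligodendrocytes 1.43, myelin 2.12, galactolipids 0.95, cholesterol 0.53, fatty acids 0.38, cell cycle -0.87, factors that hold back differentiation -0.57, microRNA targets -0.84, glutamate and GABA receptors -0.26, channels -0.19, neurons -1.09, astrocytes -0.29, microglia and macrophages 0.96, mural cells 1.2, and stress response 0.51. With the Welch statistic and cameraPR, the microRNA targets (-0.84), receptors (-0.26), channels (-0.19) and astrocytes (-0.29) no longer passed. Astrocytes did not pass with fry either (-0.29), while ganglioside synthesis did (0.25). Factors that favour differentiation, at 0.68 and just short of the threshold, passed with median centring (0.65), a trended and robust prior, the Welch statistic and fry (0.68 in each), and the mean of a gene's probe sets (0.69). For that prior and the Welch statistic the list test was cameraPR, so that these calls do not show an effect of the prior or spread alone. Notch, Wnt and BMP signalling also passed with array weights (-0.20), the mean of a gene's probe sets (-0.14) and the variance filter (-0.29), and ependyma with array weights (-0.27). The variance filter favours genes that differ between the populations, so that a pass with it is not independent support. The oxidative phosphorylation list, never past the test, turned to -0.027 with quantile normalization, -0.0232 with median centring and -0.0159 with the variance filter (9 genes). The mean of the ribosomal protein list, which never passed either, ranged from -0.66 to -0.06 over the settings that kept all 8 arrays. The lowest came from the variance filter, which keeps only the more variable members and so averages other genes. Over all 42 members the main mean was -0.07.

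With 1 array left out, list means ranged from 0.63 to 0.73 for factors that favour differentiation, from -0.22 to -0.15 for Notch, Wnt and BMP signalling, and from -0.30 to -0.15 for ependyma, each passing in some fits. Astrocyte markers ranged from -0.42 to -0.19 and did not pass without GalC+ replicate 2. Lists that never passed changed sign: oxidative phosphorylation (-0.020 to 0.0321), endothelial (-0.25 to 0.15) and erythroid markers (-0.0906 to 0.042). Apart from the stricter threshold, the cause was not tested for any of these changes.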

Other observations

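The lists described here were written after values of some of their members had been seen, so that their counts describe these arrays and are not independent evidence.

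Genes listed for the intermediate progenitors of neurons were lower in GalC+ in 8 of 10 cases and higher in none. Their mean log2 fold change was -1.53 ± 0.27 SE (exact permutation p = 0.0286, the smallest possible with 4 arrays against 4). Several of them, such as Bcl11b and Pax6, are also expressed by neurons or neural stem cells, so that the list does not mark that stage alone. Beside Eomes (-2.81), Bcl11a (-2.63), Neurod1 (-2.42) and Bcl11b (-2.41), which had shaped the choice of list, Pax6 (-1.73), Sox3 (-1.48), Nhlh1 (-1.41) and Neurog2 (-0.52) were lower. Neurog1 (-0.07, adjusted p = 0.626) and Tbr1 (0.15, adjusted p = 0.139), a factor of later neurons, did not pass the limma test.

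Mast cell genes were lower in GalC+ in 8 of 13 cases and higher in none (mean -0.85 ± 0.21 SE, exact permutation p = 0.0286). The proteases Cpa3 (-2.21), Cma1 (-2.10) and Tpsab1 (-1.46) fell with Mcpt1l1 (-2.40), as did Hdc (-0.80), which makes histamine, and the IgE receptor genes Fcer1a (-0.80) and Ms4a2 (-0.49). The mean ratio of the list was between 1.06 and 2.08 in the A2B5+ arrays and between 0.671 and 0.919 in the GalC+ arrays. Kit, which other cells of the brain also express, showed no detectable difference (0.00014, adjusted p = 0.999).

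The genes used above to weigh macrophage transcripts showed the following. The 12 border macrophage markers, among them Cd163, F13a1, Clec10a and Mrc1, rose without exception, by 2.35 (Pf4) to 5.41 (Cd163), at a mean of 3.87 ± 0.21 SE. Of these, Mrc1 was also in the fixed list of microglia and macrophage markers. Of 12 genes shared by microglia and other macrophages, 11 rose and Itgam did not pass the test (0.73, adjusted p = 0.191).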
